A study of Mus musculus with 2 samples.

How the data were processed

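Lungs of mice with K7M2 osteosarcoma that received 1V209-Cho-Lip or PBS were studied with 10x single-cell RNA sequencing, 1 library per group and 3 mice pooled per library, per the series description. Cell Ranger 9.0.1, per the file headers, made the deposited count matrices of unique molecular identifiers (UMIs) on mm10. Sequencing used an Illumina NovaSeq instrument, per the series description. The annotation release was not given in the sources used here. Of 55357 gene identifiers in the files, 52081 matched GENCODE vM21 (GRCm38, mm10), which supplied gene positions, lengths and GC content.

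The deposited barcodes numbered 13740 in the treated and 14622 in the PBS library, with 54843992 and 58156102 UMIs and a median of 2645.5 and 2376 UMIs per barcode. The lowest barcode total was 500 in both files. Barcodes needed 500 UMIs, 200 genes and at most 20% mitochondrial UMIs: 11 and 56 barcodes had too few genes and 12 and 9 too much mitochondrial RNA. The ribosomal gene Rn18s-rs5 held 6.81% and 8.51% of UMIs. Doublets were called in each library with Scrublet as carried by Scanpy, with an expected rate of 0.8% per 1000 barcodes and the automatic threshold. The calls took out 1346 (9.81%) treated and 1919 (13.2%) PBS barcodes, leaving 12374 and 12641 cells with 46745684 and 45585479 UMIs.

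Both libraries were clustered together on 2873 variable genes, the union of 2000 per library, with 30 components, 15 neighbours and Leiden resolution 2. Interferon, cytokine, MHC, stress, haemoglobin and Y-linked list genes, and mitochondrial, ribosomal, immunoglobulin and T-cell receptor genes, were left out of the clustering features. Of 56 clusters 11 were divided again at resolution 0.5, giving 81. A cluster was named by markers chosen before the data were examined, from at least 3 markers and 50% of those of a type at log2 1 or more above the rest. Of the clusters, 26 were mixed and 2 unnamed. The naming thresholds, the rule that keeps a heart-muscle cluster unnamed and the exact neighbour search were set after clusters had been seen.

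Class shares carry exact Clopper-Pearson intervals. Ratios of CPM (counts scaled to the same library total) on summed counts carry exact conditional binomial intervals. List members needed 20 UMIs over both libraries, and each list median was placed among 10000 random lists matched on mean expression, drawn from 50 genes on each side of a member. Where a count was 0, a floor of 3 counts was used for folds, and 0.5 counts were added for list medians. Class sums were made for classes with at least 50 cells in each library.

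Genes were named by rule. In the whole library these were the 10 highest and 10 lowest ratios among genes with at least 200 UMIs and 20 CPM. In a class they were the 5 highest and 5 lowest among genes with at least 100 UMIs and 50 CPM, leaving out genes below 5% of their highest class CPM. Mitochondrial, ribosomal protein, haemoglobin, variable antibody and T-cell receptor segment and predicted genes were left out of these and of the genes compared over all classes. List members named are up to 4 with the most UMIs and those with the highest and lowest ratios. Genes of the Def8-led cluster, genes higher in each class, and genes of the smaller classes and other list members named beside these were chosen after their values were seen. Some genes that these rules name are not reported here.

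Alternatives covered cell filters, doublets, clustering resolution and seed, components, denominators, thinning to 1000 UMIs per cell, which left out 962 and 1355 shallower cells, scaling by median-of-ratios and TMM, list minimums, GC-matched random lists, and sums without named cell groups. The procedure was tested on simulated data with 200 changed genes per comparison. Counts were drawn from the Poisson counting model that the intervals assume, without variation among cells, mice or libraries. The simulation thus checks the computation and not how far the intervals hold for these data. In the whole library 95.6% of intervals held the true ratio over 20409 genes, and 100% of genes raised and 100% of genes lowered 2-fold excluded 1. In neutrophil-like cells coverage was 96.0%, and 87% of lowered genes excluded 1. In general capillary endothelial-like cells coverage was 96.2%, and 96% did. Lists planted as changed lay at percentile 100 or 0, and 4 to 5% of unchanged lists lay outside the central 95%. The unchanged lists were genes drawn at random, unlike lists of genes that vary together. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.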

Results

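Neutrophil-like cells made up 35.9% against 12.4% of kept lung cells in the 1V209-Cho-Lip and PBS libraries, whereas all lymphoid classes together made up 16.2% against 37.0%. The treated library held far more RNA of the cystatin-family genes Stfa2 and Cstdc5, the acute-phase gene Saa3, Scand1 and the transcription factor gene Cebpd. It held less of Xcl1, Cd8a and the cytotoxic effector genes. Scand1 and Cebpd were higher in each class in which they were measured. Each group was 1 library, so a treatment response and a library difference cannot be told apart for these genes or for any other difference given here. Within classes, targets of NF-kB were higher in capillary endothelial, fibroblast, AT2, macrophage, B-cell and CD4 T-like cells. Counts of the neutrophil gene S100a8 were higher in these and in nearly every other class. In CD4 T-like cells the direction of the NF-kB targets turned with called doublets kept. Stress genes were also higher in the capillary endothelial, fibroblast, AT2 and interstitial macrophage-like cells. Type I interferon-stimulated genes were lower in monocyte, interstitial macrophage, CD8 T, regulatory T and fibroblast-like cells. They were lower by a smaller median in CD4 T, NK and B-cell-like cells, and higher in alveolar macrophage-like cells.

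A small unnamed cluster of cells with very many UMIs, led by Def8, Crabp2 and Col1a1, held 0.356% of treated and 1.11% of PBS cells.

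Single-cell RNA libraries were compared to ask how 1V209-Cho-Lip, which carries a TLR7 agonist, altered the cells of lungs in mice with K7M2 osteosarcoma. Each group was 1 library from the pooled lungs of 3 BALB/c females, 54843992 UMIs in 13740 barcodes for treatment and 58156102 in 14622 for PBS, so no test was made. All values are treated over PBS; intervals are 95% and describe counting error only, and percentiles place a list among 10000 expression-matched random lists as a description of these libraries. After filtering, 12374 treated and 12641 PBS cells were kept, with a median of 2513 and 2197 UMIs. The share of cells left mixed or unnamed was 4.84% against 4.95%.

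Neutrophil-like cells, known by S100a8, S100a9, Csf3r and Cxcr2, differed most among the classes in percentage points of the kept cells: 4444 and 1563 cells, 35.9% (35.1 to 36.8%) against 12.4% (11.8 to 13%), a ratio of 2.90 (2.74 to 3.08). Among immune cells alone their shares were 58.3% against 19.2%, a ratio of 3.04 (2.87 to 3.22). In the treated library the class lay mainly in clusters 0 and 2, with 22.5% and 22% of its cells, and in the PBS library in clusters 13 and 19, with 33.1% and 26.7%. Classical monocyte-like cells were also more frequent, 3.23% against 2.52% with a ratio of 1.28 (1.1 to 1.49), although at Leiden resolution 1 that ratio was 0.786. Nonclassical monocyte-like cells, which patrol vessel walls, had a share ratio of 0.337 (0.270 to 0.417).

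Every lymphoid class but plasma cells held a smaller share of the treated library. T-cell-like cells made up 9.07% against 19.8%, a ratio of 0.458 (0.426 to 0.492), and B-cell-like cells 5.53% against 11.6%, a ratio of 0.475 (0.433 to 0.521). NK-like cells made up 1.42% against 5.43%, a ratio of 0.262 (0.221 to 0.310), and CD8 T-like cells 0.404% against 2.19%, the lowest ratio of the T-cell classes at 0.184 (0.134 to 0.250). CD4 T-like cells had a ratio of 0.509, regulatory T-like cells 0.428 and gamma-delta T-like cells 0.549. With the immune cells other than neutrophils as denominator, the ratios were 0.929 for T cells, 0.964 for B cells, 0.532 (0.448 to 0.628) for NK cells and 0.374 for CD8 T cells, so the NK and CD8 T classes stayed low on this denominator while T and B cells as a whole lay near 1. On it CD4 T-like cells were at 1.03 (0.944 to 1.13), gamma-delta T-like cells at 1.11 (0.857 to 1.44) and regulatory T-like cells at 0.868 (0.742 to 1.01), intervals that each held 1.

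Macrophages and dendritic cells differed by class. Alveolar macrophage-like cells, the resident phagocytes of the air spaces, made up 2.59% against 5.87%, a ratio of 0.441 (0.385 to 0.503), and interstitial or monocyte-derived macrophage-like cells 1.81% against 2.25%, a ratio of 0.806 (0.673 to 0.963). Conventional DC-like cells had a ratio of 0.631 and pDC-like cells 0.297. Among immune cells without neutrophils, interstitial macrophage-like cells were at 1.63 (1.37 to 1.95), conventional DC-like cells at 1.28 (0.949 to 1.72), mature DC-like cells at 1.16 (0.666 to 1.98), nonclassical monocyte-like cells at 0.683, classical monocyte-like cells at 2.60 and alveolar macrophage-like cells at 0.894, so the direction of the interstitial macrophage share turned with the denominator and the DC intervals held 1.

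Of the structural classes, general capillary endothelial-like cells held the same share, 15.5% against 15.5%, a ratio of 0.999 (0.938 to 1.06), and Car4 capillary endothelial-like cells 5.30% against 6.15%. Fibroblast-like cells made up 5.64% against 3.02%, a ratio of 1.87 (1.65 to 2.12), and flat alveolar AT1-like cells 1.92% against 0.696%, a ratio of 2.75 (2.15 to 3.56), whereas the surfactant-making AT2-like cells had a ratio of 0.863. Fibroblast-like cells came mainly from clusters 36 and 39 in the treated library, with 58.0% and 21.6%, and from clusters 36 and 51 in the PBS library, with 51.6% and 20.4%. Cluster 39 held 151 treated and 76 PBS cells, and cluster 51 held 97 and 78. Dissociation sets how many structural cells enter a library, so these shares describe the suspensions.

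**Figure D1:**
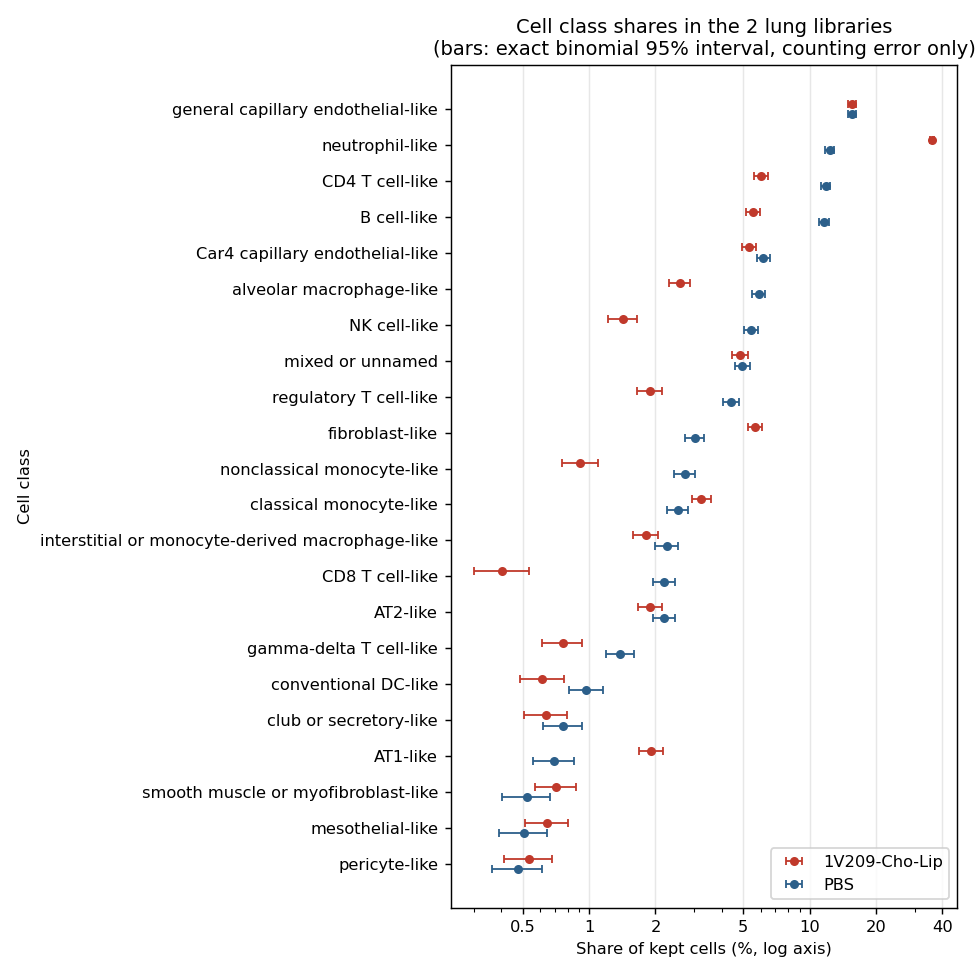
Share of each cell class among kept cells (percent, logarithmic axis) in the treated (red) and PBS (blue) libraries, with exact binomial 95% intervals.

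In the whole-library sums, the genes with the highest ratios included neutrophil cystatins, an acute-phase gene, Scand1 and a transcription factor gene. Stfa2 (ENSMUSG00000022902, chromosome 16, 36403992 to 36408457), a stefin that inhibits cysteine proteases, had a ratio of 62.7 (52.9 to 75.0), Cstdc5 (ENSMUSG00000071561, chromosome 16, 36359382 to 36367748) 39.3 (36.4 to 42.6), Stfa3 43.7 (29.6 to 67.1) and Cstdc6 25.5 (20.2 to 32.6). These paralogs are close to each other in sequence, so how their reads divide among them is uncertain. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), which encodes serum amyloid A3, had a ratio of 40.7 (35.8 to 46.4), and Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which encodes lubricin, 30.3 (24.7 to 37.6). Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15891031), induced in acute-phase responses, stood at 643 and 28.6 CPM, a ratio of 22.5 (21.3 to 23.8), and Wfdc17 (ENSMUSG00000069792, chromosome 11, 83703991 to 83706268) at 1956 and 100.9 CPM, a ratio of 19.4 (18.8 to 19.9). Scand1 (ENSMUSG00000046229, chromosome 2, 156311847 to 156312704) had a ratio of 51.5 (45.0 to 59.3), and the Ptp4a1 gene with the identifier ENSMUSG00000117310 31 (22.1 to 45.0).

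The lowest ratios belonged to lymphocyte genes and to genes of the Def8-led cluster. Xcl1 (ENSMUSG00000026573, chromosome 1, 164931644 to 164935527), the lymphotactin that NK and CD8 T cells release to draw cross-presenting DCs, had a ratio of 0.0882 (0.0736 to 0.105), the cytotoxic lymphocyte protease gene Ctsw 0.322 (0.296 to 0.350), and Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) 0.330 (0.292 to 0.372). Ly6d, a surface marker of the B lineage, was at 0.224 (0.198 to 0.254). Def8 (ENSMUSG00000001482, chromosome 8, 123423527 to 123463270) was at 740.5 and 2341 CPM, a ratio of 0.316 (0.312 to 0.320), and Hmga2 (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), a chromatin gene of embryonic and tumour cells, at 0.330 (0.306 to 0.356). Dynap had a ratio of 0.244, Tafa1 0.279, the connexin gene Gja4 0.307 and the glypican gene Gpc6 0.311.

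Part of these whole-library differences depended on how the classes were weighted. Setting class shares equal weighted each class by its average share of cells, so it also replaced the weight of its UMIs. With class shares set equal the log2 ratio of Stfa2 went from 5.97 to 3.74, of Stfa3 from 5.45 to 3.28, of Cstdc5 from 5.30 to 3.08, of Cstdc6 from 4.67 to 2.48, of Saa3 from 5.35 to 4.35, of Cebpd from 4.49 to 3.79 and of Xcl1 from -3.50 to -2.12. On the same weights Ctsw went from -1.64 to -0.35, Cd8a from -1.6 to -0.70, Ly6d from -2.16 to -1.51, Def8 from -1.66 to -0.83 and Dynap from -2.03 to -1.04. Without neutrophil-like cells Wfdc17 went from 4.27 to 2.57 and Cstdc5 to 6.02. Without the Def8-led cluster Tafa1 went from -1.84 to -0.58 and Gpc6 from -1.68 to -0.98. With the mean of each cell's CPM Prg4 went from 4.92 to 3.83 and Hmga2 from -1.6 to -2.20.

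Inflammatory cytokine and neutrophil genes were high as groups in the treated sums. The 24 measured cytokine and NF-kB target genes had a median log2 ratio of 0.44 (percentile 100), with 10 at least 1.5-fold higher and 2 lower: besides Saa3, the cytokine gene Il1b was at 3.72, the neutrophil chemokine gene Cxcl2 at 3.16, Nfkbiz at 2.44, Nfkbia at 1.25, and Il12b at 0.494. With class shares set equal this median was 0.02. Neutrophil granule genes had a median of 2.33 (percentile 100), with Mmp8 at 7.66, Lcn2 at 7.43, Ngp at 5.01, Camp at 3.10 and Mpo at 0.595, and the median was -0.14 without neutrophil-like cells. Genes associated with suppressive neutrophils had a median of 1.92 (percentile 100), or 0.10 with class shares set equal, with S100a8 at 7.42, S100a9 at 6.33 and Cd84 at 1.47.

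Interferon-stimulated genes divided. The type I list of 39 genes had a median of 0.13 (percentile 99.9): Rtp4 was at 2.63, the ubiquitin-like Isg15 at 2.34, Ifi27l2a at 1.37, Ifitm3 at 1.19, Bst2 at 0.610 and the antiviral GTPase gene Mx1 at 0.431. That median was -0.30 with class shares set equal and -0.14 without neutrophil-like cells, so its direction depended on how the classes were weighted. The interferon-gamma list had a median of -0.15 (percentile 63.2), with the feedback inhibitor gene Socs1 at 7.53 (6.59 to 8.63), Irf1 at 1.21, Gbp2 at 1.21, Iigp1 at 0.981 and Gbp8 at 0.516. Against median-of-ratios and TMM scaling, CPM ratios of the whole library were lower by a shift of 0.16 and 0.19 log2, most genes lying slightly below 1, and the interferon-gamma median turned to 0.02 and 0.05. The same scalings turned the medians of the TLR7 pathway (-0.14, percentile 65.6), the extracellular matrix genes (-0.09, percentile 68.9) and the B-cell and plasma cell genes (-0.06, percentile 75.9) positive.

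Among members of these lists, the adaptor gene Myd88 was at 2.05, the endosomal transporter gene Slc15a3 at 1.59, Unc93b1 at 0.983, Nfkb1 at 0.897, Hsp90b1 at 0.549 and Tlr9 at 0.528. In the matrix list Fn1 was at 1.92, Sparc at 0.770, Col1a2 at 0.521 and Col1a1 at 0.403, and the Def8-led cluster held 61.2% and 83.5% of the Col1a1 UMIs and 56.9% and 80.1% of those of Col1a2. Of the antibody genes Ighg2c was at 4.60 (2.56 to 8.86), Xbp1 at 1.49, Jchain at 0.971, Ighm at 0.410 and Ighg2b at 0.253. Angiogenesis and hypoxia genes had a median of 0.05 (percentile 88.8), with Vegfa at 2.30, Hif1a at 1.52, Flt1 at 1.37, Ldha at 0.886 and Kdr at 0.639.

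Genes of antigen presentation and of lymphocytes were lower in the whole-library sums, which mix class shares and expression. B-cell-like and conventional DC-like cells held smaller shares of the treated library. Within classes, given below, MHC class II genes were at like levels in B-cell-like cells and lower in macrophage-like cells. MHC class II genes had a median of -0.52 (percentile 0.37), with Cd74 at 0.698, H2-Aa at 0.732, H2-Ab1 at 0.723, Ctss at 0.821 and H2-Oa at 0.535. MHC class I genes had -0.41 (percentile 1.04), with H2-D1 at 0.975, H2-K1 at 0.886, B2m at 0.817 and Psmb10 at 0.613. Co-stimulation genes had -0.47 (percentile 0.75), with Relb at 1.41, Cd80 at 1.37, Cd83 at 0.728, Ccr7 at 0.609 and Tnfsf4 at 0.442. Cytotoxic effector genes had -1.40 (percentile 0), with 15 of 17 at least 1.5-fold lower, among them Ccl5 at 0.357, Gzma at 0.356, Nkg7 at 0.339 and Gzmk at 0.312, and Cx3cr1 at 0.809.

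Checkpoint genes had a median of -0.97 (percentile 0), although the ectonucleotidase gene Entpd1 was at 2.77 and Cd244a at 2.06 against Ctla4 at 0.510 and Cd160 at 0.384. Naive and memory genes had -0.53 (percentile 0.785), with Lef1 at 0.555, regulatory T-cell genes -0.86 (percentile 0), with Capg at 0.653 and Tnfrsf4 at 0.430, and activation genes -0.65 (percentile 0.01), with Cd44 at 1.49, Icos at 0.515 and Tnfrsf9 at 0.406. Proliferation genes had -0.71 (percentile 0), with Mki67 at 0.681, Top2a at 0.669 and Cenpf at 0.447. With class shares set equal the medians were -0.10 for the cytotoxic, -0.25 for the checkpoint, -0.25 for the regulatory, 0.10 for the naive and 0.03 for the proliferation list. These differences thus depended on how the classes were weighted. The weights differ from the sums both in class shares and in UMIs per cell, so the part of the class mix alone was not separated. The Def8-led cluster held 33.7% and 55.8% of Mki67 and 48.2% and 60.2% of Top2a UMIs, so its smaller share entered the proliferation list.

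Macrophage polarization lists differed little. M1-like genes had a median of 0.10 (percentile 94.4), with Socs3 at 2.11, Ptgs2 at 2.0 and Ccl5 at 0.357, and their direction turned with class shares set equal, with the mean of each cell's CPM and without the Def8-led cluster. M2-like genes had 0.25 (percentile 99.4), with Chil3 at 1.43, Mrc1 at 0.705 and Spp1 at 0.501 beside Vegfa and Fn1, and -0.22 with the mean of each cell's CPM. Dissociation stress genes had 0.76 (percentile 100), with Dusp1 at 7.63, Junb at 2.06, Fos at 1.69 and Hsp90aa1 at 0.715. Haemoglobin genes had -2.05 (percentile 0), with Hbb-bs at 0.274 and Hba-a2 at 0.218, and the Y-linked list had fewer than 3 measured members in these female lungs.

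**Figure D2:**
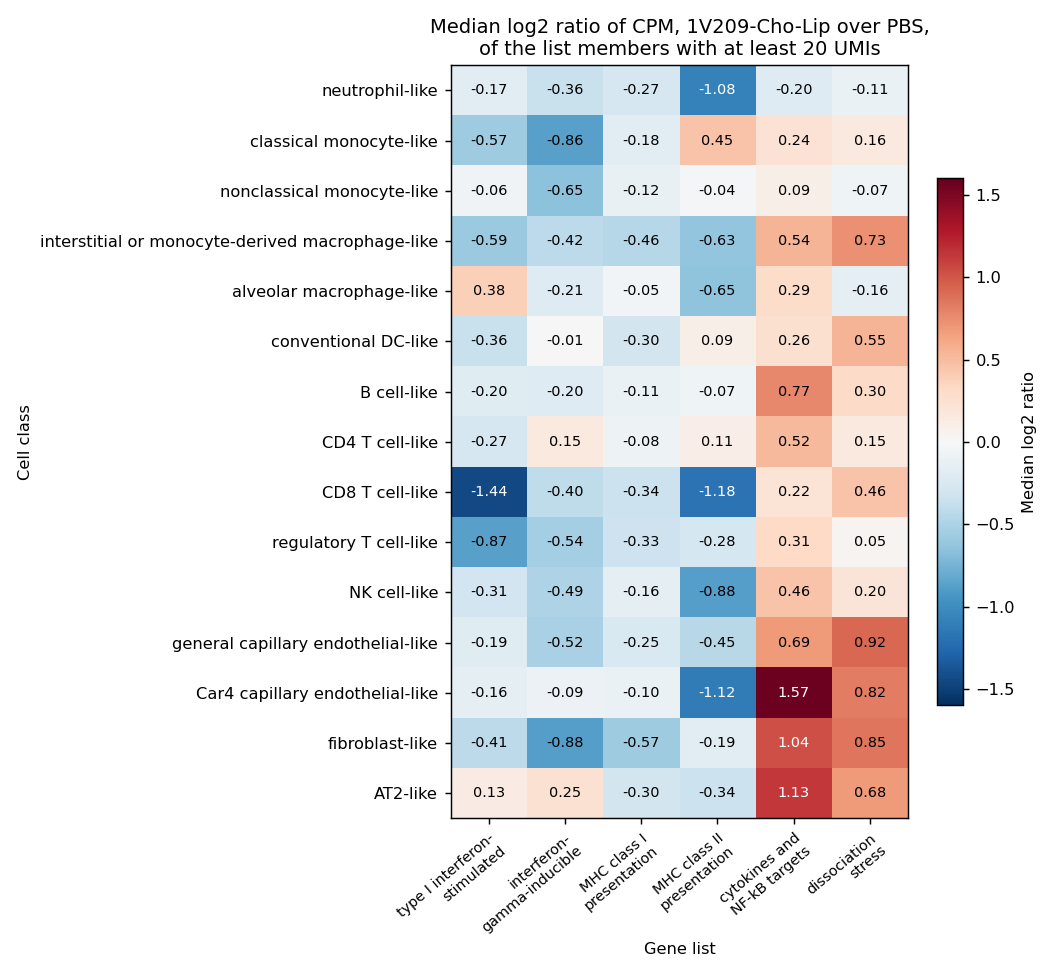
Median log2 ratio (treated over PBS, CPM) of 6 gene lists in 15 cell classes. The type I interferon, cytokine and stress medians of neutrophil-like cells, the cytokine median of CD8 T-like cells and the stress median of regulatory T-like cells turn sign under median-of-ratios and TMM scaling.

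Neutrophil-like cells of the treated library carried more RNA of the granule list and of the cystatin gene Stfa2. Wfdc17 stood at 6343 and 211 CPM, a ratio of 30.1 (27.5 to 32.9), Cebpd at 14.5 (12.2 to 17.4), Stfa2 at 13.9 (11.6 to 16.9) and Areg (ENSMUSG00000029378, chromosome 5, 91139599 to 91148432), which encodes the EGFR ligand amphiregulin, at 12.0 (7.56 to 20.3). Wfdc17, Stfa2 and Cstdc5 were also among the leading genes of clusters 0 and 2, the largest of the treated neutrophil-like cells. These held 1000 and 977 treated against 57 and 51 PBS cells. Cluster 30, led by Ngp and Camp, held 302 treated and 22 PBS cells. The mix of clusters may therefore account for part of the granule and cystatin differences. Granule genes had a median of 0.95 (percentile 99.97), with Prtn3 at 3.11 (0.999 to 15.7) on 3 PBS counts, Lcn2 at 2.05, Mmp8 at 1.95, Ngp at 1.58 and Camp at 0.990. S100a8 was at 1.62 and S100a9 at 1.36, while the whole suppressive list lay at 0.04 (percentile 75.3), with Ptgs2 at 0.609. Lower genes were Ehbp1 at 0.107 (0.0807 to 0.141), Thbs1, which encodes thrombospondin 1, at 0.274 (0.247 to 0.305), Rnase6 at 0.30, Ss18l2 at 0.333 and Def8 at 0.255.

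Il1b, Cxcl2 and Nfkbiz stood at like levels in neutrophil-like cells of both libraries, at 0.922, 0.958 and 1.00, whereas Nfkbia was at 0.670, Saa3 at 5.83 and Ccl12 at 0.160. The cytokine list had a median of -0.20 (percentile 13.1) and the type I interferon list -0.17 (percentile 17.2), with Ifitm3 at 1.37, Rtp4 at 1.07 and Isg15 at 0.784, and both turned positive under median-of-ratios and TMM scaling, which shifted this class by 0.27 and 0.26 log2. MHC class II genes had -1.08 (percentile 0), though free RNA of the scarcer B cells and DCs was not separated from their own. Interferon-gamma genes had -0.36 (percentile 6.15), with Socs1 at 8.51 (3.85 to 23.4), Cd274, the PD-L1 gene, at 0.454 and Gbp4 at 0.318. The stress list, at -0.11 (percentile 37.2), turned positive under these scalings as well.

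Classical monocyte-like cells held less interferon-response RNA in the treated library. Type I genes had a median of -0.57 (percentile 0), with 19 of 39 at least 1.5-fold lower and 0 higher: Ifit2 was at 0.348 (0.260 to 0.463), Cmpk2 at 0.372, Isg15 at 0.649, Slfn5 at 0.743, Ifitm3 at 0.837 and Lgals3bp at 1.36. Interferon-gamma genes had -0.86 (percentile 0): the CXCR3 ligand genes Cxcl9 and Cxcl10 were at 0.137 (0.0953 to 0.192) and 0.254 (0.189 to 0.339), Gbp2 at 0.545, Irf1 at 0.657 and Ifi47 at 0.574, against Socs1 at 6.15. Higher genes were Wfdc21 at 76.1 (20.9 to 632) on 2 PBS counts, Ifitm1 at 17.8 (11.6 to 29.0) and Lrg1, a secreted glycoprotein gene, at 15.1 (9.43 to 25.6), with Scand1 and Tmem160, and Plaat3 was low at 0.372. The neutrophil gene S100a8 stood at 1623 and 146 CPM in these cells, and Ifitm1 is also a leading gene of a neutrophil cluster. Saa3 was at 8.08, Il1b at 1.52 and Cxcl2 at 1.09.

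The cytokine list of monocyte-like cells had a median of 0.24 (percentile 99.7), which was -0.07 with a mitochondrial limit of 10%, and MHC class II genes 0.45 (percentile 99.9), with H2-DMb1 at 2.49, H2-Aa at 1.48 and Cd74 at 1.33. The class II direction turned with a minimum of 1000 UMIs, with the 10% mitochondrial limit and with called doublets kept. Over the alternatives the log2 ratio of Cxcl9 ranged from -2.89 to -0.62, of Cxcl10 from -2.82 to -1.09, of Ifitm1 from 2.73 to 4.27 and of Wfdc21 from 5.39 to 6.67.

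Interstitial or monocyte-derived macrophage-like cells combined high acute-phase and cell-cycle RNA with low interferon RNA. Saa3 was at 2466 and 12.1 CPM, a ratio of 203 (131 to 333), Prg4 at 52.0 (38.9 to 71.2), Cd5l (ENSMUSG00000015854, chromosome 3, 87357881 to 87371073), a secreted scavenger protein gene of tissue macrophages, at 173 (30.7 to 6864) on 1 PBS count, and the fatty-acid-binding gene Fabp7 at 57.0 (15.5 to 476) on 2. Cytokine genes had a median of 0.54 (percentile 100), with Cxcl2 at 2.0, Nfkbia at 1.82, Il1b at 1.40 and Ccl12 at 0.438. Proliferation genes had 1.15 (percentile 100), with the ubiquitin ligase gene Ube2c at 5.31, Mki67 at 2.23 and Top2a at 2.21. Type I interferon genes had -0.59 (percentile 0), with Ifit3 at 0.175 (0.101 to 0.287), Ifit2 at 0.273, Bst2 at 0.484 and Isg15 at 0.667, and MHC class II genes -0.63 (percentile 0), with Cd74 at 0.684, H2-Aa at 0.647 and Ciita at 0.505. The cell-fusion gene Dcstamp was at 0.271, Gbp8 at 0.257 and the small nuclear RNA 7SK at 0.30.

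M2-like genes of this class had a median of 0.17 (percentile 98.6), with Arg1 at 5.47, Fn1 at 4.96, Retnla at 1.16 and Spp1 at 0.528, but the median was negative with 1000 UMIs per cell, a 10% mitochondrial limit, called doublets kept or another clustering seed. Stress genes lay at 0.73 (percentile 100). Over the alternatives the log2 ratio of Cd5l ranged from 3.15 to 7.96, of Fabp7 from 5.13 to 6.15, of Prg4 from 5.64 to 6.39, of Ifit3 from -4.80 to -2.42, of Ifit2 from -3.35 to -1.02 and of Dcstamp from -2.95 to -1.78.

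Alveolar macrophage-like cells differed from the monocyte and interstitial macrophage-like cells in that type I interferon genes were higher, with a median of 0.38 (percentile 100): Ifitm3 was at 2.58, Ifi27l2a at 1.88 and Ifit3b at 17.7 (4.35 to 155) on 2 PBS counts, against Eif2ak2 at 0.593. M2-like genes had 0.86 (percentile 100), with Fn1 at 2.90, Gpnmb at 2.09, Chil3 at 1.83 and Spp1 at 0.762, and cytokine genes 0.29 (percentile 100), with Il1b at 1.71, Cxcl3 at 0.666 and Saa3 at least 10.7-fold higher against 0 PBS counts taken as 3. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499), the macrophage elastase gene, had a ratio of 10.5 (8.46 to 13.1), Wfdc17 9.36 (8.55 to 10.3) and Nenf 7.57. MHC class II genes had -0.65 (percentile 0), with Cd74 at 0.557, and among the lowest genes were Nav2 at 0.490, Def8 at 0.509, the alveolar macrophage lectin gene Siglecf at 0.559 and Adgrl3 at 0.566. With the mean of each cell's CPM the log2 ratios of Mmp12 and Wfdc17 were 2.57 and 2.5 against 3.39 and 3.23, and with a 10% mitochondrial limit that of Def8 turned to 0.07.

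General capillary endothelial-like cells held more inflammatory and immediate-early RNA, with clusters 6 and 4 making up 31.8% and 30.9% of the class in the treated and 50.6% and 24.2% in the PBS library. Cluster 10, led by Lyve1, Prss23 and Vwf, held 349 and 130 cells of the class, so part of its gene differences may come from this mix. Cytokine and NF-kB target genes had a median of 0.69 (percentile 100), with 11 of 18 at least 1.5-fold higher, among them Nfkbiz at 1.93 and Il1b at 6.34, with Nfkbia at 1.19. Stress genes had 0.92 (percentile 100), with Dusp1 at 4.74 and Junb at 2.04, and Cebpd was at 10.8 (9.81 to 11.9). The histidine decarboxylase gene Hdc at 11.1 (8.26 to 15.2) and Slfn4 at 10.2 (6.57 to 16.6) are also leading genes of neutrophil clusters, and S100a8 stood at 1531 and 83.2 CPM in these endothelial-like cells, so their source was not settled. Interferon-gamma genes had -0.52 (percentile 0), with Irf1 at 1.70, Gbp4 at 0.442 and Cxcl9 at 0.247. Lower genes were Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576), which serves fatty-acid uptake in capillaries, at 0.150 (0.118 to 0.188), Mmp15 at 0.191 (0.131 to 0.273), and the antibody genes Jchain at 0.0596, Igkc at 0.183 and Igha at 0.0971. Called doublets, when kept, brought the log2 ratio of Hdc from 3.47 to 1.75, of Slfn4 from 3.35 to 1.88, of Jchain from -4.07 to -1.81, of Igkc from -2.45 to -0.33 and of Igha from -3.36 to 0.62.

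In Car4 capillary endothelial-like cells, which lie next to AT1 cells, the cytokine list had a median of 1.57 (percentile 100), or 0.46 with called doublets kept, and the stress list 0.82 (percentile 100). Cebpd was at 16.3 (12.9 to 20.7) and Lrg1 at 10.5 (7.33 to 15.6), whose log2 ratio went from 3.39 to 2.60 with doublets kept. The xenobiotic enzyme gene Cyp1a1 was at 0.219 (0.151 to 0.310), the thromboxane receptor gene Tbxa2r at 0.332, the protocadherin gene Pcdh12 at 0.346, Ypel2 at 0.359 and Alad at 0.364. MHC class II genes had -1.12 (percentile 0), with the same doubt about free RNA.

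Fibroblast-like cells showed high NF-kB target RNA beside low interferon, MHC class I and collagen RNA. The cytokine list had a median of 1.04 (percentile 100), with 15 of 18 genes at least 1.5-fold higher: Saa3 was at 13.9 (11.6 to 16.9), Il1b at 4.48, Nfkbiz at 2.10 and Nfkbia at 1.63. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), the chemokine gene that draws B cells into follicles, was at 106 (29.1 to 875) on 2 PBS counts, Cebpd at 18.5 (16.3 to 21.1) and Marcksl1 at 13.8 (5.79 to 43.2). Interferon-gamma genes had -0.88 (percentile 0), with Cxcl10 at 0.0391 (0.0204 to 0.0688) and Irf1 at 1.63, type I genes -0.41 (percentile 0.02), with Ifit3 at 0.248 and Isg15 at 2.16, and MHC class I genes -0.57 (percentile 0). Matrix genes had -0.48 (percentile 0.01), with Col3a1 at 0.441, Col1a2 at 0.639 and Postn at 0.291 against the protease inhibitor gene Timp1 at 4.09. Cluster 51, with Dcn and Col3a1 among its leading genes, held 97 of 698 treated and 78 of 382 PBS cells of the class. Part of the matrix difference may come from this mix.

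The antiprotease gene Slpi was at 0.190 in fibroblast-like cells, and antibody RNA was far lower, with Ighg1 at 0.00242 (0.000498 to 0.00712) on 3 treated counts, Jchain at 0.00842 and Igkc at 0.0346. Over the alternatives the log2 ratio of Cxcl13 ranged from 5.24 to 7.0, of Cxcl10 from -4.71 to -2.78, of Marcksl1 from 2.48 to 4.05, of Slpi from -2.5 to -1.08, of Ighg1 from -8.73 to -6.05, of Jchain from -7.11 to -2.01 and of Igkc from -5.10 to -1.91. AT2-like cells had a cytokine median of 1.13 (percentile 100), a stress median of 0.68 (percentile 100) and a proliferation median of -0.88 (percentile 0), with Cebpd at 14.4 (12.1 to 17.3), the cyclin gene Ccnd1 at 0.405, Sfn at 0.347 and Krtap17-1 at 0.170. AT1-like cells had the immediate-early gene Egr1 at 14.4 (7.21 to 33.6) and the collagen chaperone gene Serpinh1 at 0.328.

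B-cell-like cells held MHC class II and plasma cell genes at like levels in the 2 libraries, with medians of -0.07 (percentile 10.2) and 0.00 (percentile 43.1), while cytokine genes had 0.77 (percentile 100) and type I interferon genes -0.20 (percentile 0.96), and S100a8 stood at 338 and 58.7 CPM. Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620) was at 0.362 (0.314 to 0.416) within B cells, the histone deacetylase gene Hdac9 at 0.449, Kmo at 0.523 and the BH3-only gene Pmaip1 at 0.524, and Sdhaf1 was at 8.86. Clusters 41 and 40 made up 49.9% and 44.7% of these B-cell-like cells in the treated and 66.7% and 29.5% in the PBS library. Part of the gene differences may come from this mix. In CD4 T-like cells Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536) was at 14.1 (10.0 to 20.3), the CD40 ligand gene Cd40lg at 0.496 and AW112010 at 0.584. Their type I interferon median was -0.27 (percentile 0) and their cytokine median 0.52 (percentile 100), which became -1.08 and -0.10 with called doublets kept, as the log2 ratio of Cd40lg went from -1.01 to -0.13.

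The CD8 T-like cells of the treated library, only 50 and 277 cells in the 2 libraries, had less interferon and effector RNA. Type I genes had a median of -1.44 (percentile 0), or -0.64 with doublets kept, with 27 of 33 at least 1.5-fold lower: Ifit3 was at 0.0840 (0.0100 to 0.311) on 2 treated counts, Isg20 at 0.277 (0.136 to 0.509) and Isg15 at 0.291 (0.178 to 0.453). Cytotoxic genes had -0.54 (percentile 0), with Gzma at 0.337 and Ccl5 at 0.616, Xcl1 was at 0.176 (0.0930 to 0.306) and Cd8a itself at 0.287 (0.170 to 0.456). Cd8a is a defining marker of this class, which was named on both libraries together. The class name is therefore less certain for the 50 treated cells, which may include cells of other types. Whether this accounts for part of the interferon and effector differences was not tested. Dusp1 was at 5.38 (4.10 to 7.08) and the adhesion gene Alcam at 3.73 (2.60 to 5.33). Interferon-gamma genes had -0.40 (percentile 0.015), turning to 0.03 with doublets kept, and over the alternatives the log2 ratio of Cd8a ranged from -2.07 to -0.57, of Xcl1 from -3.67 to -1.79, of Ifit3 from -3.84 to -2.91, of Isg15 from -2.05 to -0.78 and of Alcam from 0.78 to 1.91. Median-of-ratios and TMM scaling shifted this class by -0.26 and -0.27 log2.

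Regulatory T-like cells held more IL-17 RNA: Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496), the cytokine gene of Th17 and gamma-delta T cells, was at 211 and 12.7 CPM, a ratio of 16.6 (11.2 to 25.6), and the adjacent Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617) at 16.3 (8.20 to 36.7). With another clustering seed these log2 ratios were 5.37 and 4.88 against 4.05 and 4.02, and 2.95 and 3.19 with the mean of each cell's CPM. Type I interferon genes had a median of -0.87 (percentile 0), with 27 of 35 at least 1.5-fold lower, among them Ifit1 at 0.170 (0.103 to 0.268), Isg20 at 0.405 and Isg15 at 0.406, and the PD-L2 gene Pdcd1lg2 was at 0.400. Their own list had -0.22 (percentile 1.44), with Ctla4 at 0.773, Tnfrsf4 at 0.685 and Il2ra at 1.06, and proliferation genes 0.58 (percentile 99.99), with Mki67 at 1.61 and Ccnb2 at 1.79. Cluster 53, led by cell-cycle genes, made up 14.6% of the class in the treated and 9.17% in the PBS library, and cluster 17 the rest. Its cells had a median of 13290 UMIs against 2718.5 in cluster 17, so they weighed more in the summed counts. The mix of clusters may account for the proliferation genes and for part of the Il17a and Il17f differences. Which cells of the class held the Il17a and Il17f RNA was not tested.

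NK-like cells, though fewer, kept their cytotoxic genes, with a median of 0.12 (percentile 97.2): Ccl5 was at 1.28, Gzma at 1.12, Nkg7 at 1.03 and the fractalkine receptor gene Cx3cr1 at 3.55, against the TRAIL gene Tnfsf10 at 0.178. Xcl1 was at 0.246 (0.193 to 0.310), Fchsd2 at 0.234, the phosphatase gene Inpp4b at 0.339 and Pkp4 at 0.382. Type I interferon genes had -0.31 (percentile 0.05), interferon-gamma genes -0.49 (percentile 0) and proliferation genes -0.98 (percentile 0.49).

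No cluster met the osteosarcoma-like marker rule, so cells named by it were below 0.0242% of treated and 0.0237% of PBS cells, the level of 3 cells, which sets no limit on tumour cells that lack these markers. Of 11 osteoblast and osteosarcoma genes, 4 were measured, with a median of -0.54 (percentile 10.6): Runx2 was at 0.858, Alpl at 0.787 and Phex at 0.60. The unnamed Def8-led cluster held 44 and 140 cells, 0.356% (0.258 to 0.477%) against 1.11% (0.932 to 1.31%), a ratio of 0.321 (0.223 to 0.453). Its leading genes included Def8, Crabp2, Il1rl1, Prl2c2, Lgals1, Col1a2, Col1a1, Ccl2 and Serpinh1, and it held 93.1% and 95.4% of all Def8 UMIs and 93.1% and 92.2% of those of Hmga2. Its cells carried 5.74% and 13.8% of the UMIs of the libraries. Within it, Runx2 was at 41.0 CPM against 48.9 in all other cells and Mki67 at 266, whereas the fibroblast gene Dcn was at 94.3 CPM against 2450 in fibroblast-like cells.

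RNA of a given class was also counted in the others, and it differed between the libraries. S100a8, a neutrophil gene, stood at 1531 and 83.2 CPM in general capillary endothelial-like cells, 2010.3 and 206 in fibroblast-like cells and 234 and 41.6 in CD4 T-like cells, and these classes had suppressive neutrophil list medians of 2.91, 2.46 and 2.08. Hbb-bs, from red cells, stood at 99.0 and 936 CPM in neutrophil-like, 37.2 and 740.3 in B-cell-like and 245 and 755 in general capillary endothelial-like cells. Def8 stood at 35.6 and 139.7 CPM in neutrophil-like and 31.4 and 99.8 in CD4 T-like cells. Il1b in structural cells, Hdc and Slfn4 in endothelial-like cells and the antibody genes in endothelial and fibroblast-like cells moved with these RNAs, and the cytokine list and the stress list were high in the same classes. S100a8 was also higher in NK-like (820 and 74.3 CPM), regulatory T-like (336 and 24.5) and CD8 T-like cells (176 and 20.5). Of the classes summed only nonclassical monocyte-like cells had it lower, at 202 and 225 CPM. A higher S100a8 count therefore did not by itself mark the classes with a high cytokine list.

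A set of genes was higher in each class in which it was measured. It holds Scand1, Cebpd, Tmem160, Nenf, Wfdc21 and Marcksl1, so their values given above for single classes are not particular to those classes. Haemoglobin genes, which were lower across classes, were left out of this set with the other genes that the naming rule leaves out. Of the remaining 4652 genes measured in at least 8 of 21 classes, 39 were at least 2-fold higher in the treated library in each and 0 were lower in each. The median fold over classes was 49.1 (25.9 to 79.8, 16 classes) for Scand1, 14.5 (4.98 to 87.9, 14 classes) for Cebpd, 12.7 (6.72 to 17.3, 9 classes) for Tmem160, 9.89 (6.62 to 18.4, 21 classes) for the cytokine receptor gene Il31ra, 7.44 (3.84 to 12.7, 19 classes) for the translation factor gene Eif3f, 6.49 (5.09 to 10.4, 9 classes) for C1qbp, 6.13 (4.22 to 10.8, 15 classes) for the iron-sulfur scaffold gene Iscu and 5.78 (4.90 to 10.2, 9 classes) for the mediator gene Med30.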

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

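The alternatives with another clustering seed, without neutrophil-like cells, without the cluster of highest UMI count, with immune cells without neutrophils as denominator, without members at free RNA level, without class-uniform genes, without Rn18s-rs5 and with GC-matched lists were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and for the same reason no test was repeated. Dropping the UMI minimum moved nothing, since the lowest barcode total was 500.

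With at least 1000 UMIs per cell the neutrophil-like share ratio was 3.27 of kept and 3.37 of immune cells. The type I interferon median of interstitial macrophage-like cells was -0.76, while the MHC class II median of monocyte-like cells and the M2 median of interstitial macrophage-like cells turned to -0.071 and -0.0068. With cells thinned to 1000 UMIs the neutrophil-like ratios were 3.25 and 3.34. The cause was not tested for the medians.

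With immune cells other than neutrophils as denominator the share ratios were 0.929 for T, 0.964 for B, 0.532 for NK and 0.894 for alveolar macrophage-like cells, and turned to 1.63 for interstitial macrophage and 1.28 for conventional DC-like cells, because this denominator is smaller in the treated library. At Leiden resolution 1 the classical monocyte-like share turned to 0.786 of kept and 0.828 of immune cells, and the type I interferon median of that class was -0.35. The cause was not tested.

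Median-of-ratios and TMM scaling add a constant to each median. The neutrophil granule median in neutrophil-like cells became 1.22 and 1.21, and in the whole library the type I interferon median 0.30 and 0.33, the interferon-gamma median 0.016 and 0.049 and the cytokine median 0.60 and 0.64.

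With called doublets kept the granule median in neutrophil-like cells was 1.01. Directions turned for MHC class II in monocyte-like cells (-0.21), M2 in interstitial macrophage-like cells (-0.047), Igha in general capillary endothelial-like cells (0.62), the cytokine list in CD4 T-like cells (-0.10) and interferon-gamma genes in CD8 T-like cells (0.026). With a mitochondrial limit of 10% the type I interferon median of interstitial macrophage-like cells was -0.75, and the cytokine and MHC class II medians of monocyte-like cells turned to -0.066 and -0.0076, the M2 median of interstitial macrophage-like cells to -0.019 and Def8 in alveolar macrophage-like cells to 0.073. The cause was not tested.

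With the mean of each cell's CPM the type I interferon median of interstitial macrophage-like cells was -0.32, and in the whole library the interferon-gamma median was -0.46 and the M2 median turned to -0.22. Another clustering seed gave -0.75 for type I interferon genes and -0.023 for M2 genes in interstitial macrophage-like cells. List members of at least 50 UMIs gave a cytokine median of 1.14 in general capillary endothelial-like cells. The cause was not tested.

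With class shares set equal the whole-library medians were -0.30 for type I interferon, -0.23 for interferon-gamma and 0.022 for cytokine genes, and turned to 0.10 for naive T-cell and 0.030 for proliferation genes. Without the cluster of highest UMI count the type I interferon and interferon-gamma medians were 0.029 and -0.48. Without neutrophil-like cells they were -0.14 and 0.056, with 0.37 for cytokine and -0.14 for granule genes.

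In all, including the values above, 194 share values of kept cells stayed, 16 moved and 3 reversed, and of immune shares 90 stayed, 3 moved and 1 reversed. Of gene ratios 1156 stayed, 202 moved and 2 reversed, and of class list medians 747 stayed, 99 moved and 10 reversed. Of whole-library list medians 189 stayed, 127 moved and 6 reversed. A list median counted as reversed only where its main percentile lay outside the central 95%. Other turns of sign given above were counted as moved or stayed. A share counted as reversed only where its main interval excluded 1. The neutrophil-like share ratio ranged from 2.86 to 3.27.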

Other observations

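The tests of depth per cell, dilution and doublets were chosen after seeing the data, and the others before.

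Smaller classes held further differences. Conventional DC-like cells had the resistin-like gene Retnla at 0.0129 (0.00155 to 0.0472) on 2 treated counts, Cxcl10 at 0.291 (0.177 to 0.460) and Irf1 at 0.361 (0.256 to 0.502). Gamma-delta T-like cells had a median interferon-gamma list log2 ratio of -0.87 (percentile 0), with Gbp2 at 0.306 and Irf1 at 0.370, and nonclassical monocyte-like cells -0.65 (percentile 0). Mesothelial-like cells, which line the pleura, had the acute-phase genes Serpina3n and Hp at least 33.5-fold and 18.5-fold higher and Cxcl2 at 59.2 (20.1 to 289) on 3 PBS counts, but S100a8 stood at 1455 and 10.2 CPM there and Hp is also a leading neutrophil gene, so neutrophil RNA may account for part of this. In smooth muscle or myofibroblast-like cells Col3a1 was at 0.103, Eln at 0.234 and Acta2 at 0.337, genes picked after their values were seen. S100a8 stood at 4525 and 35.3 CPM in that class, so neutrophil RNA differed there as well. Club-like cells had the antibacterial lectin gene Reg3g at 6.85 (3.93 to 12.9).

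The genes Scand1, Cebpd, Tmem160 and Il31ra belonged to a set of 39 that was higher by at least 2-fold in each measured class. Reads shared with other genes were argued against, since 1.28% of their 3' words occurred elsewhere against 0.502 to 8.30% in matched sets, and over the set the highest class stood in the median only 2.05 times above the median class, which argued against free RNA from another cell type except for members such as Lcn2, at 2240.2 CPM in neutrophil-like and 71.7 CPM in general capillary endothelial-like cells. Their median GC content of 51.1% lay above the 45.7 to 50.8% of matched sets. Their longest transcripts were also short, with a median of 1998 bases against 2810 to 4459 in matched sets, a comparison without a written prediction. A difference in library preparation tied to GC content or transcript length may have contributed and stays open. A response to the treatment shared by all cells and a difference between the libraries cannot be told apart for these 39 genes, because each group was 1 library. The same limit holds for every other difference between the groups.

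Neutrophil-like cells held a larger share of the treated library. Leaving out cells under 1000 UMIs, more of them in the PBS library, by itself gave a ratio of 3.27, and thinning the rest to 1000 UMIs gave 3.25 (3.06 to 3.46), so equal depth did not remove the difference. Of the PBS neutrophil-like cells, 5.37% (4.31 to 6.61%) lay in the lowest UMI range above the floor of 500. This was below the limit set beforehand for a loss under the floor to be the cause. In the treated library the value was 1.28% (0.973 to 1.66%), and median UMIs were 2285 in treated and 1386 in PBS neutrophil-like cells. No deposited barcode had under 500 UMIs, so such a loss could not be seen and stays open. Dilution of the other cells by neutrophils would leave the lymphoid to endothelial ratio unchanged, yet it was 0.454 (0.421 to 0.490). An effect of 1V209-Cho-Lip, differences among the pooled mice and differences in dissociation were not tested and stay open.

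The unnamed cluster led by Def8, Crabp2 and Col1a1 was 3.11-fold (2.21 to 4.48) smaller in the treated library. Doublets were argued against by its median of 51736.5 UMIs. The richest classes with at least 50 cells in each library, conventional DC-like and AT2-like cells, had 8713 and 7641. The 2 small plasma cell clusters had 22138 and 11017.5. The median CPM of 5 fibroblast markers, Dcn, Inmt, Mfap4, Pdgfra and Tcf21, was 0.333% of the fibroblast-like median, which argued against fibroblasts that express them. The fibroblast markers Col1a1 and Col1a2 went the other way, at 1182 and 1303 CPM against 585 and 840 in fibroblast-like cells. Collagen-rich fibroblasts low in the 5 markers were therefore not argued against by this. The cluster's median log2 ratios to fibroblast-like cells differed among chromosomes with a standard deviation of 0.355 (0.325 to 0.400), from 0.76 on chromosome 15 to -0.38 on chromosome 9, against at most 0.0876 in the 8 other non-immune classes. A hypothesis is that these cells may be K7M2 tumour cells with unequal chromosome copies. Whether their lower share reflects less tumour in the treated lungs was not tested, because each share describes 1 dissociated suspension per group. Sp7 at 0.335 CPM and Ibsp at 0 left the osteoblast identity open, and the origin was not tested in another way.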
